A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

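Unsynchronised budding yeast cells carried a constitutive Myc-tagged histone H3 and a Flag-tagged histone H3 that galactose switches on. DNA bound to each tag was immunoprecipitated, amplified and hybridised together to one 2-colour tiling array per time point, with Myc in the red channel and Flag in the green channel per the labels. There were 8 arrays: 2, 30, 45, 60, 90, 120 and 150 minutes in galactose, and 1 named midlog, which has no time in minutes. Each group holds 1 array and no dye was swapped, so no time point has a replicate check. Every p-value therefore measures only the spread between these arrays, which mixes time with technical error.

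The deposited scanner files hold median spot intensity and local background for each channel, in intensity units, without scanner normalization per the file headers. A flag per spot was also deposited; its code is in other units, and spots with a negative flag were left out. The percent of saturated pixels of each spot was deposited as well, per the file headers, and saturated spots were kept. The header of the midlog scan names another strain than the labels and cells grown in galactose to mid-logarithmic phase. The 90-minute and midlog arrays were scanned on another day than the other 6 arrays. The authors also deposited a value table in log2 units, with 20792 probes. It correlated at 0.674 to 0.972 with the scanner log2 Flag/Myc ratios after each probe was centred on its mean over the 8 arrays, so the direction is Flag over Myc. Its probe levels are lost by that centring, and the authors' normalization before it is not given in the sources used here. Column medians of the table ran from -0.038 at 60 and 90 minutes to 0.124 at 2 minutes.

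Here the ratio of each spot was log2 of Flag over Myc after subtraction of local background, centred on the median of its array, without loess. Centring makes every value relative to the middle of its own array, so a total gain of Flag-H3 over time is not measured. From 70.9% of the 24960 probes on the midlog array to 92.5% at 90 minutes were used. After subtraction of background, the median Flag signal of used spots was 1.57 times the median background at 2 minutes and 11.15 times at 120 minutes. The median Myc signal, computed alike, was 4.31 to 6.71 times background. For arrays, the number of arrays limits the precision.

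The probes are 50 bases long, start about every 20 bp and come without gene names. Overlapping probes were joined into 219 contigs with 505.8 kb of sequence. Contigs were matched to the R64 gene table by start codon, stop codon and open reading frame, together with the spacing of the probe numbers. Chromosomes were kept mainly where at least 70% of their contigs matched, so the lowest share kept, 71.0%, partly follows from that rule. With 5 shuffled gene tables the highest share was 43.5%. This placed 193 contigs with 23331 probes (93.5%) on 12 chromosomes, 13815 of them on chromosome III. Of the 193, 16 had no accepted reading-frame match of their own and were placed by probe number between placed contigs of the same chromosome. Their frames were not required to be open where the placed contigs lay close on both sides. The regions of GIP3, ATP1, ALG3 and HMRA1 named below lie on such contigs. The other 26 contigs, with 1629 probes, entered no comparison by location. No genome sequence was used here and the build behind the array is not given in the sources used here, so gene names, classes and chromosomes are printed without base positions. Replication origins and centromeres were planned as classes and are not analysed here, since the gene table lists none. The MAT locus was not covered by placed probes.

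Promoters were the 500 bp upstream of a start codon outside other coding sequence. Coding sequence was divided into its first 500 bp, its last 500 bp and the part between, called mid-coding. Genes too short to hold both ends in full were divided at their middle and had no mid-coding part. Mid-coding probes came from 154 genes, against 424 for 5′ coding ends, 253 for 3′ coding ends and 406 for promoters. Class differences from mid-coding thus mix position with the length and set of genes, and are not taken within genes. Transfer RNA genes took 100 bp on each side, the silent mating loci 500 bp, and subtelomeres 10 kb from a chromosome end. A region was the mean of at least 3 probes of one gene and class. Of 1266 regions, 1134 had a value on all 6 arrays from 30 to 150 minutes and 1114 on all 7 timed arrays. A mean of 35.2% of promoter probes and 51.3% of tRNA gene probes had no usable spot, against 8.1% of mid-coding probes.

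Regions were tested with limma 3.58.1 in R 4.3.3, as the mean against the array median over the 6 arrays from 30 to 150 minutes and as a slope on time over the 7 timed arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. On data simulated for 1134 regions the first test found 84.5% of shifts of 0.5 log2 units and 99.5% of shifts of 1. For 1114 regions the slope test found 0% of slopes of 0.25 and 60.5% of slopes of 0.5 log2 units per hour. Classes were compared with mid-coding by an exact two-sided sign-flip permutation test over the 6 arrays, whose smallest p is 0.0312. Class differences were set against time by Pearson and Spearman correlation with exact permutation. The median of each gene list was ranked among 10000 random lists of the same size and kind of region, and lists with at least 3 measured members were tested by the sign-flip test. In list counts and tests, a measured member had a value on all 6 arrays. Coding regions of list members, over whatever part of the gene the probes covered, were adjusted apart from the other regions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

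Named genes were the 10 highest and 10 lowest regions past the threshold with the same sign on all 6 arrays, at most 1 region per gene and direction, the same for slopes with no test claimed where fewer passed, and the measured members of the gene lists. The tests, gene lists, classes, this rule and the alternatives were chosen before the data were examined, except where the text says otherwise. The lists were the galactose regulon, highly transcribed genes, amino acid biosynthesis and uptake, ribosome biogenesis, mating, silent mating genes, histone genes, phosphate, mitochondrial, heat and stress, and cell cycle transcripts. Alternatives covered the background, loess, scaling, the authors' value table, spot filters, probe minimum, promoter length, GC content, the 2-minute array as background, other time windows and each array left out.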

Results

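The data were 8 two-colour tiling arrays that set newly made Flag-tagged histone H3 against Myc-tagged H3 along parts of the yeast genome, mostly chromosome III. The design asks where galactose-induced H3 enters chromatin of cells that were not synchronised, and how soon. Between 17700 and 23079 spots were used per array. Ratios on the arrays from 30 to 150 minutes correlated across probes at 0.696 to 0.922, and with the 2-minute array at 0.309 to 0.645, the earliest array and the one used as background. Probes are not independent replicates. All ratios below are log2 Flag/Myc with the array median at 0.

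Ratios of Flag-H3 were higher at promoters and at the few tRNA genes measured than in coding sequence, and lowest in the middle of coding sequence. Over 30 to 150 minutes, 290 of 336 promoters lay above the array median and 7 below. Of 137 mid-coding regions, 7 lay above and 112 below. The first 500 bp of coding sequence lay between these, with 178 of 413 regions above and 95 below, and the last 500 bp had 69 of 243 above and 104 below. All 5 tRNA genes tested were above, with a mean over genes of 1.59 against 0.93 for promoters. In total 549 regions were above and 318 below by limma at an adjusted p of 0.05, among 1134 tested.

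The highest region was the 5′ coding end of YCR006C on chromosome III, at 3.34 ± 0.79 (SD, n = 6; limma adjusted p = 9.59e-07), against 0.89 at 2 minutes. The promoter of AGP1, an amino acid permease gene on chromosome III, stood at 3.24 ± 0.91 (SD, n = 6; limma adjusted p = 2.00e-06), against 0.53 at 2 minutes. The promoter of HEM12, a heme biosynthesis gene on chromosome IV, stood at 2.89 ± 0.88 (SD, n = 6), against 0.38 at 2 minutes. CIT2, which encodes the peroxisomal citrate synthase, had a promoter mean of 2.70 ± 0.49 (SD, n = 6), against 1.59 at 2 minutes. The promoters of SPL2 (2.87), ATG41 (2.71) and PRE7 (2.69), and the 5′ coding ends of SDH6 (3.30) and BAP3 (2.71), were among the same 10. BAP3 encodes a branched-chain amino acid permease and PRE7 a proteasome subunit. The regions of YCR006C and CIT2 lie on the same contig, as do those of BAP3 and HEM12, so the 10 regions are not all separate stretches of the genome. SUP53, a leucine tRNA gene on chromosome III, reached 3.07 ± 0.95 (SD, n = 6) but already stood at 2.08 at 2 minutes. The limma adjusted p of these 10 regions was at most 7.11e-06.

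The lowest region was the mid-coding part of TRP5, the tryptophan synthase gene on chromosome VII, at -1.51 ± 0.19 (SD, n = 6; limma adjusted p = 6.06e-07), with -0.91 at 2 minutes. The mid-coding part of PAT1, an mRNA decapping factor gene on chromosome III measured by 69 probes, stood at -1.17 ± 0.16 (SD, n = 6), with -0.74 at 2 minutes. FIG2, a mating-induced cell wall protein gene measured by 163 mid-coding probes, stood at -1.06 ± 0.32 (SD, n = 6), with -0.74 at 2 minutes. The mid-coding parts of SHY1 (-1.30), RSA4 (-1.13), ALG3 (-1.12) and EHT1 (-1.11), the 3′ coding ends of RAV2 (-1.13) and DSC2 (-1.07), and the 5′ coding end of YOL162W (-1.07) made up the rest. The limma adjusted p of these 10 regions was at most 1.27e-05. With the 2-minute array subtracted, the test is against a region's own 2-minute value and no longer against the array median. The subtraction was made probe by probe, over probes used on both arrays. Its result can therefore depart from the difference between a region's printed mean and its printed 2-minute value. By it, 385 regions were above their 2-minute value and 303 below, among 1088. Of the regions tested both ways, 304 were above the median and above their 2-minute value, and 175 below both. Another 57 were above the median but below their 2-minute value, and 17 the reverse.

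**Figure D1:**
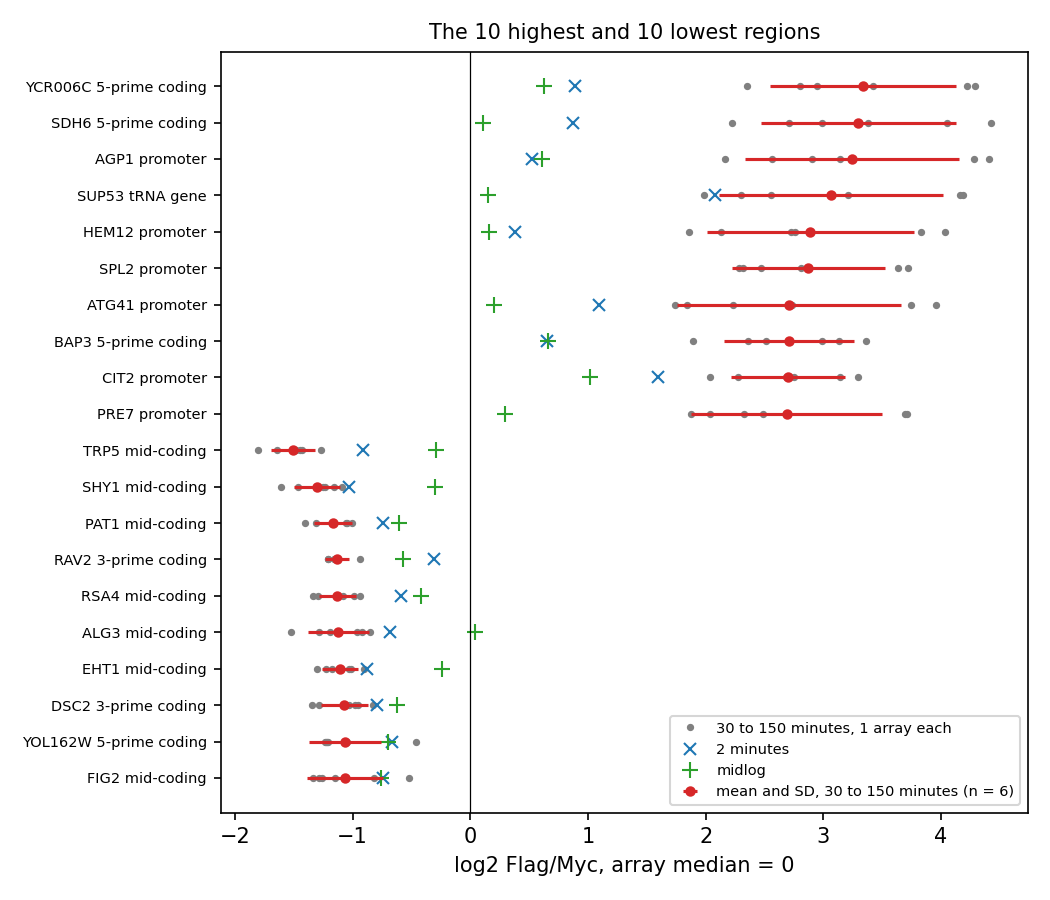
Log2 Flag/Myc on the horizontal axis for the 10 highest and 10 lowest regions, with 1 grey point per array from 30 to 150 minutes, the mean and SD of the 6 arrays in red, the 2-minute array as a cross and midlog as a plus sign. The highest mean is 3.34 at YCR006C and the lowest is -1.51 at TRP5.

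By class of location, promoters exceeded mid-coding sequence by 1.54 ± 0.34 (SD, n = 6; exact permutation p = 0.0312, adjusted p = 0.0365), a 2.92-fold higher ratio, on 6 of 6 arrays. Between probes matched on Myc signal, an alternative added after seeing the data, the difference was 0.85 ± 0.23 (SD, n = 6). The difference was 0.63 at 2 minutes, 1.33 at 30 minutes, 2.00 at 45 minutes and 1.15 at 150 minutes. The tRNA genes exceeded mid-coding by 2.11 ± 0.59 (SD, n = 6; exact permutation adjusted p = 0.0365), but by 1.67 already at 2 minutes, and by 1.29 without the dimmest 25% of spots. Other intergenic sequence was 1.21 ± 0.25 (SD, n = 6) above mid-coding, with 0.76 at 2 minutes, and 0.75 above it matched on Myc signal. The 5′ coding ends were 0.67 ± 0.14 and the 3′ coding ends 0.51 ± 0.11 above it (SD, n = 6), with 0.11 and 0.09 at 2 minutes. The silent mating loci HML and HMR, whose genes are kept repressed, were 0.38 ± 0.12 (SD, n = 6) above mid-coding and 0.43 above it at 2 minutes. Their difference was 0.76 with flagged spots kept, 0.22 with loess, 0.21 matched on Myc signal and 0.155 without the dimmest 25% of spots, where it no longer passed. Other intergenic sequence, both coding ends and the silent mating loci had the same exact permutation adjusted p of 0.0365. Subtelomeres differed by 0.33 ± 0.31 (SD, n = 6; exact permutation adjusted p = 0.0625) and did not pass.

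With the 2-minute array subtracted, promoters were still 0.78 ± 0.29 above mid-coding, 5′ coding ends 0.54 ± 0.13, 3′ coding ends 0.40 ± 0.11 and other intergenic sequence 0.31 ± 0.22 (SD, n = 6), each on 6 of 6 arrays but with an exact permutation adjusted p of 0.0547. These 4 classes were at the smallest p that 6 arrays allow, and 5 of the 7 must be for any to pass. The tRNA genes were left with 0.36 ± 0.58 and the silent mating loci with -0.09 ± 0.15 (SD, n = 6; exact permutation adjusted p = 0.219 for each).

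**Figure D2:**
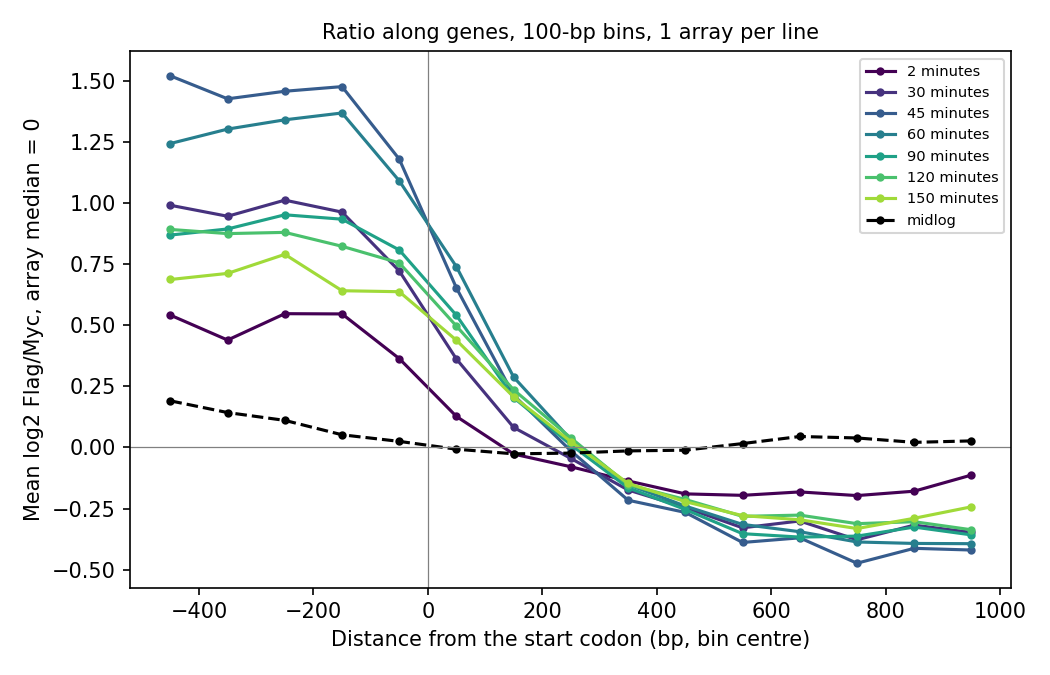
Mean log2 Flag/Myc against the distance from the start codon in bins of 100 bp, 1 line per array. At 45 minutes the ratio runs from 1.52 in the bin farthest upstream to -0.42 in the bin farthest into coding sequence, and on the midlog array from 0.19 to 0.03.

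No region passed the test for a straight-line change over 2 to 150 minutes. With limma, 0 regions rose and 0 fell at an adjusted p of 0.05 among 1114, while 73 rising and 93 falling had an unadjusted p under 0.05. The steepest upward slopes, none past the threshold, were at the 5′ coding end of GIP3 (0.90 per hour, SE 0.17, limma adjusted p = 0.118), the 5′ coding end of MPF1 (0.86) and that of AGP1 (0.85). The 3′ coding end of PGK1, the phosphoglycerate kinase gene, had a slope of 0.77 per hour (SE 0.13, limma adjusted p = 0.0963). The 5′ coding end of ARO10, a phenylpyruvate decarboxylase gene, had 0.72 per hour (SE 0.10, limma adjusted p = 0.0568). YCR024C-B (promoter, 0.67), YAP1802 (0.64), HIS3 (0.64), RPL28 (0.60) and BUD31 (0.59) completed the upward 10. The steepest downward slopes, also not past the threshold, were at the YCL042W promoter (-0.66 per hour, SE 0.15, limma adjusted p = 0.149), the proline tRNA gene SUF2 (-0.59) and the tRNA gene YNCC0010C (-0.50). The promoters of HMRA1 (-0.50), TAF2 (-0.45), PAT1 (-0.44) and TRX3 (-0.39), the mid-coding part of EAF7 (-0.46), the 3′ coding end of YCR090C (-0.43) and the 5′ coding end of YBR221W-A (-0.42) completed the downward 10. On log2 of minutes 28 regions rose and 3 fell. Over 45 to 150 minutes only, a window chosen after seeing the data, 31 rose and 133 fell, and 21 rose and 74 fell with each array also divided by its median absolute deviation.

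The differences of promoters, tRNA genes and other intergenic sequence from mid-coding were highest at 45 minutes, those of both coding ends at 60 minutes, and all were lower at 150 minutes. With each array divided by its median absolute deviation, promoters (1.89) and tRNA genes (2.70) were highest at 60 minutes and the silent mating loci (0.60) at 2 minutes. Subtelomeres stood at 0.76 at 45 minutes, -0.01 at 90 minutes and 0.31 at 150 minutes, and the silent mating loci between 0.25 and 0.54 on the timed arrays, without one rise and fall. Over the 7 timed arrays the promoter difference had a Pearson r with time of 0.114 (exact permutation p = 0.808, adjusted p = 0.943) and a Spearman rho of 0.107 (exact permutation p = 0.840). The silent mating loci had the lowest r of the 7 classes, -0.538 (exact permutation p = 0.212, adjusted p = 0.695; rho -0.607, exact permutation p = 0.167), and the 5′ coding ends the highest, 0.476 (exact permutation p = 0.290, adjusted p = 0.695; rho 0.321, exact permutation p = 0.498). No adjusted p was under 0.695. The 2 arrays farthest from the median time were those at 120 and 150 minutes. Without them r was 0.649 for promoters, -0.238 for the silent mating loci and 0.835 for 5′ coding ends. Both arrays left out come after the highest promoter difference, and the 2-minute array was kept. These values thus do not show whether r rests on the 2-minute array. Among the arrays scanned on the first day, which leaves out 90 minutes, the r of promoters was 0.1003, of silent mating loci -0.576 and of 5′ coding ends 0.455. The other scan day holds 1 timed array and gives no value.

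**Figure D3:**
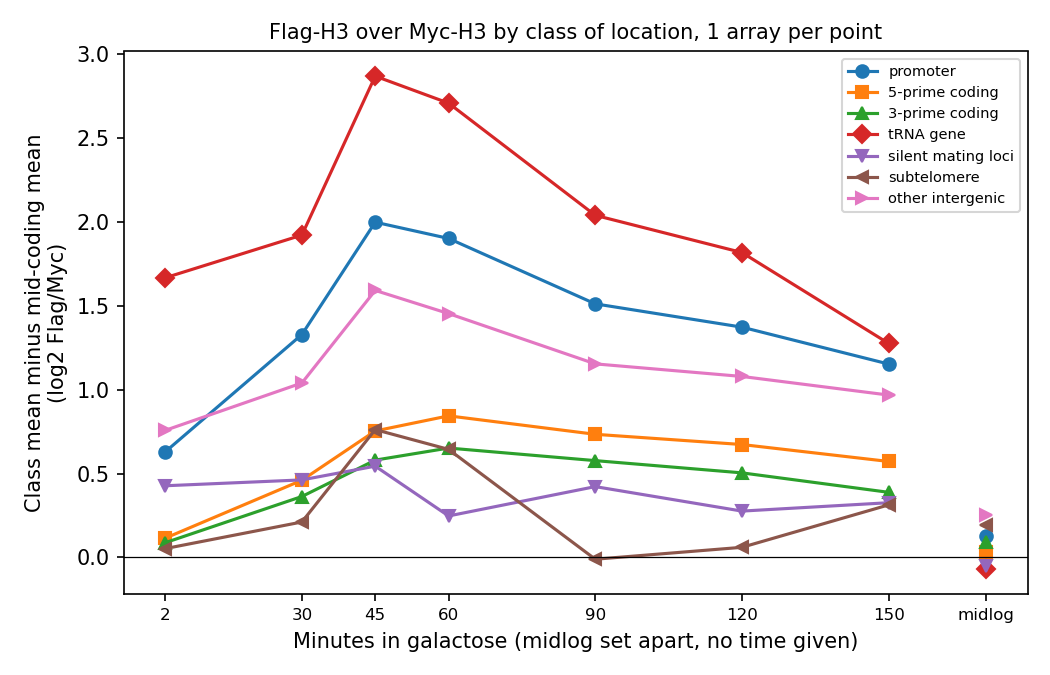
Difference between the mean log2 Flag/Myc of each class and that of mid-coding sequence against minutes in galactose, 1 array per point, with midlog set apart on the right. The tRNA gene difference is 2.87 at 45 minutes and 1.82 at 120 minutes, and the promoter difference 2.00 and 1.37.

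No gene list passed its test. Over 10 list tests at least 7 must reach the smallest exact p of 0.0312 for any to pass, and 6 did, each with an adjusted p of 0.0521. After subtraction of the 2-minute array 7 of 9 list tests were at that p, where 6 are enough. Whether a list passes thus rests on how many others sit at that p, and only sizes are given for the subtracted ratios. All 9 measured promoters of highly transcribed genes were above the array median, over all regions and adjusted over the list alone, as were 86.3% of all promoters tested, with a list median of 1.60 at the 99.7th percentile of random promoter lists. Their mean exceeded that of all promoters by 0.59 ± 0.13 on 6 of 6 arrays (SD, n = 6; exact permutation p = 0.0312, adjusted p = 0.0521), and by 0.17 with the 2-minute array subtracted, or 0.03 then without PGK1. Examples were CIT2, PGK1 (2.03 ± 0.69), PDI1, which encodes protein disulfide isomerase (1.84 ± 0.39), and ELO2, a fatty acid elongase gene (1.70 ± 0.44; SD, n = 6). The promoter of RPS14A, a ribosomal protein gene, was below its own 2-minute value with that array subtracted (-0.81, limma adjusted p = 0.000507). That of SRO9 did not differ from its 2-minute value (-0.08, limma adjusted p = 0.598). Of 9 coding regions in this list, 5 were above and 2 below the median, by both adjustments. RPS14A coding sequence, among the 5, stood below its own 2-minute value (-0.35, limma adjusted p = 0.0140). PGK1 stood at 1.16 ± 0.62, RPL28 at 1.52 ± 0.45, GLK1, the glucokinase gene, at 0.84 ± 0.44, and ABP1, an actin-binding protein gene, at -0.58 ± 0.12 (SD, n = 6). The coding mean exceeded that of all coding regions by 0.26 ± 0.22 (SD, n = 6; exact permutation adjusted p = 0.0781), by 0.12 without RPL28, and by 0.02 with the 2-minute array subtracted, and its median lay at the 97.8th percentile.

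All 5 promoters of the amino acid list with a value on all 6 arrays were above the median by both adjustments. Of these, AGP1, LEU2 (2.01 ± 0.42) and HIS4 (1.49 ± 0.38; SD, n = 6) were the highest. The HIS3 promoter, at 2.31 over the 3 arrays that measured it, and that of ILV6, at 0.79 over 5, were not tested. The list exceeded all promoters by 0.78 ± 0.18 (SD, n = 6; exact permutation adjusted p = 0.0521), with its median at the 96.5th percentile, and by 0.40 with the 2-minute array subtracted. Without AGP1 the difference was 0.39 as measured and -0.10 with that subtraction. The CHA1 promoter in this list did not pass with the 2-minute array subtracted (-0.18; limma adjusted p = 0.135). Of its 7 coding regions 2 were above, AGP1 (1.62 ± 0.57) and HIS3 (2.18 ± 0.57), and 2 below, HIS4 (-0.47 ± 0.26) and THR4 (-0.42 ± 0.21, SD, n = 6), by both adjustments. HIS3 was covered only at its 5′ coding end, by 6 probes, and 25 of the 36 AGP1 probes lay at its 5′ coding end. Both are thus set mainly as 5′ ends, a higher class, against coding regions covered more fully. The coding mean exceeded that of all coding regions by 0.26 ± 0.28 (SD, n = 6; exact permutation adjusted p = 0.104), with the median at the 53.3rd percentile, and by 0.39 with the 2-minute array subtracted. Without AGP1 and HIS3 the other 5 coding regions lay -0.33 from all coding regions as measured and -0.23 with that subtraction. Leaving out list members was chosen after seeing the data.

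All 4 measured promoters of ribosome biogenesis genes were above the median by both adjustments, and the list lay -0.11 ± 0.20 from all promoters (SD, n = 6; exact permutation adjusted p = 0.219). Of its 5 coding regions 3 were below by both adjustments, PWP2 (-0.61 ± 0.18), SPB1 (-0.34 ± 0.30) and BUD23 (-0.24 ± 0.20, SD, n = 6). The list lay -0.37 ± 0.22 from all coding regions (SD, n = 6, exact permutation adjusted p = 0.0521), and -0.20 with the 2-minute array subtracted. With 1 member left out, the subtracted difference ran from -0.41 without BUD23 to -0.08 without SPB1. The medians lay at the 37.6th percentile for promoters and the 18.3rd for coding regions. BUD23 coding sequence did not pass with loess (0.06, limma adjusted p = 0.571). It was above its own 2-minute value with that array subtracted (0.80, limma adjusted p = 1.46e-05).

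All 3 measured promoters of the mating list were above the median, yet the list lay -0.31 ± 0.15 from all promoters, and its coding regions, 1 above (KAR4) and 3 below, lay -0.52 ± 0.09 from all coding regions (SD, n = 6; exact permutation adjusted p = 0.0521 for each). Adjusted over the list alone the counts were the same, and the medians lay at the 20.5th and 8.74th percentiles. The list differences with the 2-minute array subtracted were -0.56 for the 2 promoters left, without a test, and -0.55 for coding regions. Without FIG2 the coding difference was -0.30 as measured. The FIG2 promoter was below its own 2-minute value with that array subtracted (-0.28, limma adjusted p = 0.0362), and its means over all used probes differed by -0.11. With that subtraction the FUS1 promoter (-0.10) and KAR4 coding sequence (-0.22) did not pass in either direction (limma adjusted p = 0.347 and 0.0507). Over all used probes the FUS1 promoter mean lay 0.009 above its 2-minute mean. Of 6 measured promoters of the list named mitochondrial 5 were above. This list lay -0.28 ± 0.13 from all promoters (SD, n = 6, exact permutation adjusted p = 0.0521), with the median at the 26.1st percentile. Of its 7 coding regions 3 were above over all coding regions and 2 adjusted over the list alone, with NFS1, a cysteine desulfurase gene, below at -0.63 ± 0.27 (SD, n = 6). The coding mean lay -0.11 ± 0.07 from all coding regions (SD, n = 6; exact permutation adjusted p = 0.0781), although the list median, at the 71.6th percentile, lay above theirs. After the same subtraction the list differences were -0.40 for promoters and -0.35 for coding regions. As measured, they were -0.15 for promoters without IMG2 and 0.01 for coding regions without NFS1. The NFS1 promoter (-0.41) and the MRPL32 (-0.39) and RIM1 (-0.24) coding sequences were below their own 2-minute values with that array subtracted (limma adjusted p at most 0.0140). The IMG1 promoter (-0.23) did not pass (limma adjusted p = 0.136).

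The other lists had fewer than 3 measured regions of each kind and no test of the list. Of the galactose regulon only GAL4 coding sequence was measured, by 29 probes, at -0.52 ± 0.08 (SD, n = 6, limma adjusted p = 5.20e-05). HMLALPHA1 coding sequence was below at -0.85 ± 0.24 and HMRA1 coding sequence above at 0.30 ± 0.32 (SD, n = 6, limma adjusted p = 1.31e-05 and 0.0289). HMRA1 coding sequence stood at 0.74 at 2 minutes and was below that value with the 2-minute array subtracted. Probes at HML and HMR can also bind DNA of the MAT locus. The promoter of PHO87, a phosphate transporter gene, stood at 2.13 ± 0.60 and its coding sequence at -0.18 ± 0.11 (SD, n = 6). The coding sequences of the stress genes HSP30 (-0.69 ± 0.13) and CPR4 (-0.68 ± 0.10) were below (SD, n = 6; limma adjusted p at most 1.17e-05). The HCM1 promoter stood at 1.281 ± 0.241 and its coding sequence at -0.27 ± 0.31, and CDC10 coding sequence at -0.10 ± 0.17 (SD, n = 6; limma adjusted p = 0.281 for CDC10). HCM1 coding sequence did not pass with the 2-minute array subtracted (0.18; limma adjusted p = 0.152). Histone genes were not analysed here, as no placed probe covered one.

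On the midlog array the promoter and tRNA gene contrasts were small. Promoters stood 0.13 above mid-coding, 5′ coding ends 0.03, 3′ coding ends 0.09, other intergenic sequence 0.25 and subtelomeres 0.19, while tRNA genes stood at -0.07 and the silent mating loci at -0.05. The AGP1 promoter was at 0.61, the CIT2 promoter at 1.02, SUP53 at 0.15 and mid-coding TRP5 at -0.30. The SD of all ratios was 0.45, against 0.74 at 2 minutes and 1.16 at 45 minutes. Midlog ratios correlated across probes at 0.319 to 0.483 with the arrays from 30 to 150 minutes, at 0.387 with the 90-minute array scanned on the same day, and at 0.359 with 2 minutes. With 1 midlog array this comparison has no replicate check.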

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

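Of the 26 contigs that could not be placed on a chromosome, and so entered no comparison, 11 had mean ratios above their 2-minute value on all 6 later arrays, as did 93 of the 193 placed contigs. Of those 11, 10 lay above the array median over 30 to 150 minutes, and the highest had 1.70 ± 0.52 (SD, n = 6) against 0.25 at 2 minutes over 53 probes.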

How the results depend on the processing

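Alternatives added after seeing the data were chromosome III only, the 45 to 150 minute window, matching on Myc signal, list members left out and, for slopes, GC content regressed out. The cause of a change was not tested unless stated. The count of regions above the median fell to 361 without the dimmest 25% of spots, which leaves 834 regions to test, and on chromosome III only, with 491 regions, 211 were above and 160 below. Other settings stayed within 1.5 times of 549 above and 318 below, where the 2-minute subtraction counts regions above and below their own 2-minute value. With each array left out the counts were 521 to 554 and 287 to 308. For slopes, 0 rising and 0 falling became 1 rising with foreground intensity, with scaling by the median absolute deviation or with GC content regressed out, 6 rising and 2 falling with flagged spots kept, 3 rising without the dimmest 25%, 10 rising in the authors' value table, 28 rising and 3 falling on log2 of minutes, and 31 rising and 133 falling over 45 to 150 minutes, or 21 and 74 when also scaled by the median absolute deviation; leaving out each array gave 0. With the 2-minute array subtracted the class differences from mid-coding were 0.78 (promoter), 0.54 (5′ coding), 0.40 (3′ coding), 0.36 (tRNA gene), 0.31 (other intergenic) and -0.094 (silent mating loci), none past the threshold. With 30 to 60 minutes only they were 1.74, 0.69, 0.53, 2.50, 1.36 and 0.42, and 3 arrays cannot give an exact p under 0.25. With 1 array left out, where 5 arrays cannot give an exact p under 0.0625, they ran from 1.45 to 1.62, 0.64 to 0.72, 0.48 to 0.54, 1.95 to 2.27, 1.14 to 1.26 and 0.35 to 0.41. Without the dimmest 25% the silent mating loci had 0.155 and did not pass (exact permutation adjusted p = 0.0729) and tRNA genes 1.29. The silent mating loci had 0.76 with flagged spots kept and 0.22 with loess. Matching on Myc signal gave 0.85 for promoters, 0.75 for other intergenic sequence and 0.21 for the silent mating loci. Subtelomeres passed with the midlog array added, at 0.31, and on chromosome III only, at 0.41. With the 2-minute array subtracted, 7 of 9 list tests stood at the smallest exact p, against 6 of 10 before, and this number took them across the threshold: highly transcribed (0.17) and amino acid promoters (0.40), amino acid (0.39), ribosome biogenesis (-0.20), mating (-0.55) and mitochondrial coding regions (-0.35) and mitochondrial promoters (-0.40). Of these only amino acid and mitochondrial coding regions reached a smaller exact p than before, while mating promoters, with 2 members left, stood at -0.56. For the amino acid list, promoters without AGP1 stood at 0.39, or -0.098 with the 2-minute array subtracted, and coding regions without AGP1 and HIS3 at -0.326 and -0.23. With the 2-minute array subtracted, signs turned for RPS14A promoter (-0.81) and coding (-0.35), SRO9 promoter (-0.081), CHA1 promoter (-0.18), BUD23 coding (0.80), FIG2 promoter (-0.28), FUS1 promoter (-0.10), KAR4 coding (-0.22), HMRA1 coding (-0.57), IMG1 promoter (-0.23), NFS1 promoter (-0.41), MRPL32 coding (-0.39), RIM1 coding (-0.24) and HCM1 coding (0.18), and with loess for BUD23 coding (0.061). With the 2-minute array subtracted, a sign refers to a region's own 2-minute value over probes used on both arrays, and not to the array median. Over all used probes the FUS1 promoter mean lay 0.009 above its 2-minute mean, so its turned sign rests on the probes kept. Of 1630 comparisons of a named region with an alternative, 1526 kept sign and side of the threshold, 69 fell short of it, 20 passed it newly and 15 turned sign. The authors' value table was not run for levels, classes or lists, because its probes are centred, and the probe minimum does not apply to classes. At 2 minutes the background-subtracted Flag signal was 1.57 times background, the lowest multiple of the arrays, which limits the use of that array as background. The median Flag signal itself was 2481 there and 2303 at 60 minutes, and the Flag background of 1582 at 2 minutes was the highest.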

Other observations

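The fits over 45 to 150 minutes, the matching on Myc signal at tRNA genes, the reading of the planned 2-minute subtraction as a test of background there and the tests of turned channels and of the scan day were chosen only after the results were seen. The window starts at the array where the promoter contrast was highest, so falling promoters in it partly restate that choice, and over 30 to 150 minutes 0 regions rose and 0 fell by limma (105 and 173 at an unadjusted p under 0.05). Over 45 to 150 minutes 102 of 336 promoters fell and 0 rose by limma, 3 of 5 tRNA genes fell, and of 138 mid-coding regions 16 rose and 1 fell. The steepest falls were at the promoters of SDH6 (-1.45 log2 units per hour), AGP1 (-1.37), HEM12 (-1.34), ATG41 (-1.22) and PRE7 (-1.18), the tRNA genes SUF2 (-1.37) and SUP53 (-1.32), and the 5′ coding ends of YBR221W-A (-1.38) and YCR006C (-1.17). The steepest rises were in the mid-coding parts of PGK1 (0.75) and ATP1, a mitochondrial ATP synthase gene (0.75), and at the 5′ coding end of ARO10 (0.71). The 3′ coding end of GBP2 (0.66) and mid-coding CHA1 (0.65) came next. At PGK1 the promoter ratio fell by 1.06 per hour while the middle of its coding sequence rose. Mid-coding PDI1, PBN1 and SAT4 rose by 0.54, 0.54 and 0.53 per hour, and the 3′ coding ends of RVS161 and SRO9 by 0.54 and 0.52. With each array divided by its median absolute deviation the promoter difference from mid-coding was 1.87 at 45 minutes, 1.89 at 60 minutes and 1.22 at 150 minutes, and 21 regions rose and 74 fell in this window. Of these, 54 promoters and 3 tRNA genes fell and 0 of either rose, and 10 mid-coding regions rose and 0 fell. Across all regions the slope in this window correlated at -0.563 with the mean ratio. Within classes it was -0.548 among promoters, -0.672 among 5 tRNA genes, -0.362 at 5′ coding ends, -0.353 at 3′ coding ends and -0.051 among mid-coding regions. Across classes and among promoters the counts are thus not separate from the level of a region. Among mid-coding regions, level and slope were hardly related. Slope and mean come from the same arrays.

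For promoters above mid-coding sequence, 3 technical explanations were tested. With the 2-minute array subtracted a difference of 0.785 ± 0.293 (SD, n = 6) was left, which argues against background at 2 minutes as the whole cause. With GC content regressed out it was 1.513 ± 0.335, and between probes matched on Myc signal it was 0.846 ± 0.229 (SD, n = 6), each above 0 on 6 of 6 arrays. The 2-minute background and dim Myc spots could thus account for part of the 1.54, but none of the 3, taken alone and as tested, for all of it. The 3 were not removed together, so these values do not show whether they could jointly account for it. The Flag signal at 2 minutes, 1.57 times background, limits the first of these tests. Myc signal is also the denominator of the ratio, so the lower value after matching cannot be assigned to dim spots alone. Faster entry of new H3 at promoters stays a hypothesis found and tested on the same arrays.

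For tRNA genes above mid-coding sequence, the difference left after subtraction of the 2-minute array was 0.357 ± 0.585 (SD, n = 6) and below 0 on 1 array, so background present at 2 minutes may account for most of it. Matching on Myc signal left 1.431 ± 0.558 (SD, n = 6), which argues against dim Myc spots as the whole cause. Early entry of H3 at tRNA genes was not told from background by these tests and stays open.

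The midlog array correlated at 0.319 at the lowest with a timed array, which argues against turned channels. Neighbouring probes correlated at 0.698 on it, below the lowest timed array (0.721 at 2 minutes), as predicted for spot noise. Such a correlation also falls where real contrasts are small, so this test cannot decide whether spot noise contributes. The 90-minute array, scanned on the same day, had a promoter minus mid-coding difference of 1.512, which argues against the scan day as the whole cause, though this test was set with that value known. The growth state that the labels name and the other strain in the scan header stay open and were not tested.

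For slopes on time the real order of the 7 arrays gave 0 regions, so all 100 orders drawn reach that count by construction and say nothing about chance; the highest count of another order was 58.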
